A study of Mus musculus with 6 samples.

How the data were processed

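Total RNA of C57BL/6 mouse cerebellum was extracted with TRIzol, depleted of ribosomal RNA, converted to biotin-labelled sense-strand cDNA and hybridised to Affymetrix mouse exon arrays, per the labels' protocols. The age in the labels put 3 arrays in the P7 group and 3 in the 6wk group, and the replicate numbers come from the titles. The labels do not say whether replicates are separate animals, so p-values measure only the spread between these samples, which may in part be technical. The Y-linked gene Eif2s3y read 10.49 in 6wk replicate 1 and 5.60 and 5.42 in 6wk replicates 2 and 3, so these arrays did not all carry the same RNA.

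The deposited values are on the log2 scale, with array minima from 1.91 to 2.09 and maxima from 14.2 to 14.4. RMA (background correction, normalization between arrays and probe summary), Affymetrix Power Tools and the mm9 genome are named in the submitters' processing notes, with no versions. Any filter and the exact order of steps are not given in the sources used here. Of the 23750 rows, 3945 hold values of 5 decimals or fewer, 19702 equal means of 2 to 60 such values, and 103 fit neither pattern. A row is therefore read as the mean of a gene's probe-set values, with a median of 7 averaged. A mean over probe sets can hide a change in a single exon, and no exon-level value was analysed here. The array medians ranged from 7.82 to 7.97, and the values were used as deposited.

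Rows were named from the array's annotation table: 18463 rows have 1 gene symbol, 1799 several and 3488 none. Symbols were compared with a RefSeq gene table of assembly GRCm38.p6, used for names only, which changed 0 symbols. For the 471 genes with more than 1 row, the row with the highest mean over all 6 arrays was kept, which left 17858 genes. No row with several symbols was used for a gene. Listed genes that share a row with another gene or have no row of their own were not analysed here, among them Tet1. No per-sample column was left unused.

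Each row was fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) for the difference 6wk minus P7, two-sided, with no block, and Benjamini-Hochberg adjusted p-values under 0.05 were called. Gene-level results were adjusted over the 17858 genes. The 28 gene lists, fixed with their members before the data were examined, were cell cycle; granule neuron progenitor and Sonic hedgehog response; immature neuron, axon growth and migration; mature granule neuron; Purkinje cell; GABAergic interneuron; Bergmann glia and astrocyte; oligodendrocyte precursor; myelin and mature oligodendrocyte; microglia; endothelial cell and pericyte; choroid plexus and ependyma; meninges and fibroblast; blood cell; tissue next to the cerebellum; DNA methylation and 5-hydroxymethylcytosine; synaptic vesicle and synapse; GABA-A receptor subunit and chloride transporter; ionotropic glutamate receptor subunit; voltage-gated potassium and sodium channel; extracellular matrix and perineuronal net; cholesterol synthesis and turnover; mitochondrial respiration; glycolysis; ribosome biogenesis; imprinted growth genes; immediate early gene; and antigen presentation and complement. Some genes are members of more than 1 list. Each list was tested with limma's camera at its preset correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation and with fry, which asks whether a list's genes move on balance one way and does not compare them with other genes. Of the 18 lists that passed camera, 0 passed with an estimated correlation (adjusted p from 0.329 to 0.432) and 17 with fry. Correlation between genes does not by itself account for these losses. The antigen presentation list had an estimated correlation of -0.089, below the preset. Its unadjusted camera p still went from 0.0084 to 0.04997.

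The named genes were chosen by a rule also fixed before the data were examined. It takes the 6 largest rises and 6 largest falls among called genes whose groups do not overlap, up to 2 rises and 2 falls per list by the same criteria, and a fixed set of genes whatever their result, of which Tet1, Tet2, Tet3, Dnmt1, Dnmt3a and Dnmt3b are named here and the rest is not reported here. The rule gave 81 measured genes, of which 78 were called. Genes named outside it are marked as named after their values were seen. Levels are means ± SD over 3 arrays, and SE is that of the limma difference.

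The steps were tested on simulated data for the comparison of 6wk with P7, with 3 simulated arrays per age and 200 of 17858 genes changed. Of the genes changed 2-fold 66% were called, and of those changed 4-fold 89%, with the right sign in 100%, and 3.98% of all calls fell on unchanged genes. The list shifted in the simulation was called, and 0 of 27 unshifted lists were. Each gene was drawn independently, with the same spread at both ages. In the data the estimated correlation was 0.895 for the cell cycle list. The simulation therefore says nothing about false calls under correlated genes or unequal spread.

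Alternatives planned before the data were examined were a filter on dim rows, a further quantile normalization, centring on array medians, a trended robust prior, array weights, the replicate number as a block, averaging the rows of a gene, an unequal-variance test per row, the other list tests and leaving out each array in turn. Leaving out P7 replicates 2 and 3 together was added after seeing the data. The closing section gives their effects. Figures were drawn with matplotlib 3.10.9.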

Results

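RNA from the cerebellum of C57BL/6 mice was measured on Affymetrix mouse exon arrays, which carry probes along the exons of each gene. The arrays formed 2 age groups of 3 replicates each: P7 (7 days after birth) and 6wk (6 weeks of age). According to the series description, the comparison served to find expression changes that go with changes in 5-hydroxymethylcytosine, the oxidised form of 5-methylcytosine that TET enzymes produce. Each array gave 23750 values on the log2 scale, with medians from 7.92 to 7.97 at P7 and from 7.82 to 7.88 at 6wk. The number of arrays limits the precision of every value, and the labels do not say that the replicates came from separate animals.

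The P7 arrays differed among themselves, and P7 replicate 2 stood apart. Gabra6, the GABA-A receptor subunit typical of cerebellar granule neurons, read 10.56 and 9.36 in P7 replicates 1 and 3 but 4.91 in replicate 2. Pcp2, a Purkinje cell gene, read 9.52, 6.18 and 8.75 in P7 replicates 1, 2 and 3. Slc6a3, the dopamine transporter, read 6.78, 10.76 and 9.84 in the same order, and Tph2, the enzyme of neuronal serotonin synthesis, read 5.43, 9.12 and 8.70. These genes were chosen after their values were seen. Across the 23750 rows, P7 replicate 2 correlated with P7 replicates 1 and 3 at r = 0.952 and r = 0.978, while the 6wk arrays correlated with each other at 0.984 to 0.989 (correlations across rows, which are not independent replicates). In all, 55 genes were over 4-fold higher and 97 over 4-fold lower in P7 replicate 2 than in P7 replicate 1, against 10 and 2 between 6wk replicates 2 and 1. List medians without P7 replicate 2 therefore stand beside the list results below. Values with P7 replicate 1 alone at P7, an alternative added after seeing the data, are given for some of the calls that it changed. With 1 array that fit measures no spread at P7, so calls gained or lost in it rest on the spread of the 6wk arrays.

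**Figure D1:**
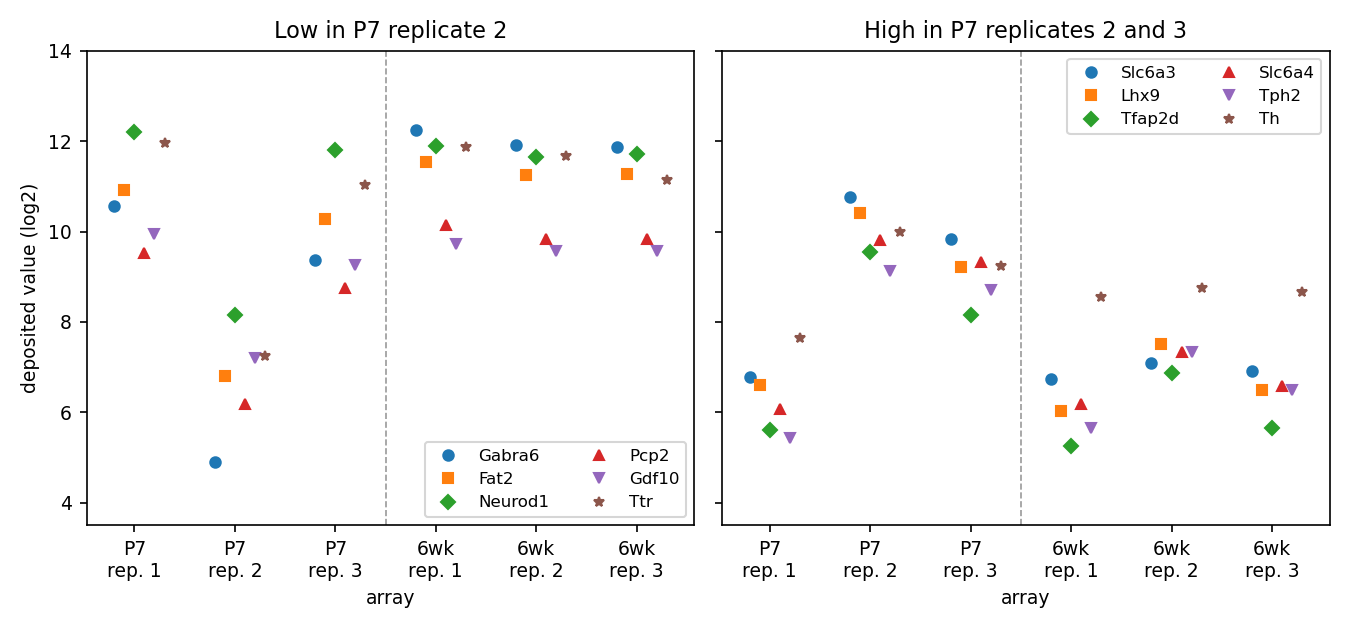
Deposited log2 value (vertical axis) of 12 genes on each of the 6 arrays (horizontal axis); each point is a gene on an array, and the dashed line separates the ages. In the left panel the genes are lowest in P7 replicate 2 (Gabra6 4.91), and in the right panel they are higher in P7 replicates 2 and 3 than in P7 replicate 1 (Slc6a3 10.76 and 9.84 against 6.78).

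Between P7 and 6wk, 3870 of 17858 genes (21.7%) passed the limma test. At 6wk, 1475 of them were higher and 2395 lower, and 320 and 626 of these differed by at least 2-fold. Lower genes made up 61.9% of the calls with the deposited scaling, but 45.4% after a further quantile normalization and 44.8% after each array was centred on its median, so the balance of directions depended on the scaling. At the level of single rows, 4300 of 23750 transcript clusters passed, 1627 higher and 2673 lower at 6wk. All 3870 called genes had groups whose values did not overlap, as had 42.1% of all genes tested, where chance gives 10%. Without P7 replicate 2 the test called 4781 genes, 1708 higher and 3073 lower, and 3594 genes were called in the same direction both ways. Leaving out P7 replicate 3 or any 6wk array cut the calls to 682 to 833 higher and 965 to 1253 lower genes, and 1517 of the 3870 genes were called in each of the 6 fits that leave out an array.

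Among called genes, the largest rises in the deposited values were in Etnppl, Crtam, Cbln3, Dao, Aqp6 and Chil5. Etnppl, which breaks down phosphoethanolamine and is expressed in astrocytes, rose from 5.05 ± 0.12 (SD, n = 3) at P7 to 9.48 ± 0.25 (SD, n = 3) at 6wk (log2 difference 4.44, SE 0.15, limma adjusted p = 0.000346). Crtam, an immunoglobulin-family adhesion molecule, rose by a log2 difference of 4.02 (SE 0.28, adjusted p = 0.000700), and Dao, the enzyme that oxidises D-serine, by 3.51 (SE 0.16, adjusted p = 0.000419). Aqp6, an aquaporin, and Chil5, a chitinase-like protein, rose by 3.20 and 3.11. Cbln3, a granule neuron cerebellin, differed by 3.74 with all arrays and by 2.76 without P7 replicate 2, and its call was lost without P7 replicate 3 (adjusted p = 0.0571) and without any 6wk array (0.0697 to 0.0759). Except for Cbln3, the P7 means of these genes (5.05 to 6.41) lay below the first quartile of every array (6.89 to 7.03). Background levels were not analysed here, so the size and rank of such differences are uncertain.

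Among called genes, the largest falls in the deposited values were in Pclaf, Ccna2, Dcx, Top2a, Nusap1 and Bub1. Ccna2, the cyclin of S and G2 phase, fell from 10.16 ± 1.23 (SD, n = 3) to 6.06 ± 0.05 (SD, n = 3), a log2 difference of -4.10 (SE 0.56, limma adjusted p = 0.00472). Dcx, the microtubule protein of migrating neurons, fell from 11.20 ± 0.85 (SD, n = 3) to 7.22 ± 0.32 (SD, n = 3), a log2 difference of -3.98 (SE 0.42, adjusted p = 0.00205). Top2a and Nusap1, which act on chromosomes and the spindle in dividing cells, fell by 3.80 and 3.62. Pclaf, a PCNA-binding protein, differed by -4.18 and lost its call without P7 replicate 3 (adjusted p = 0.0511) or 6wk replicate 1 (0.0522). Bub1, a spindle checkpoint kinase, differed by -3.58 and lost its call without P7 replicate 3 (adjusted p = 0.0501). All these falls were larger without P7 replicate 2, for example -4.79 for Ccna2 and -4.45 for Dcx. Except for Dcx, the 6wk means of these genes (4.44 to 6.06) lay below the first quartile of every array, with Top2a (4.44) and Bub1 (4.58) under the median level of olfactory receptor genes (4.64), so the size and rank of these falls are uncertain too. The lower group mean of Sox4, Postn, Mrc1, Kcnq5, Opalin, Pdgfra and Uhrf1, named below, also lay under that quartile.

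**Figure D2:**
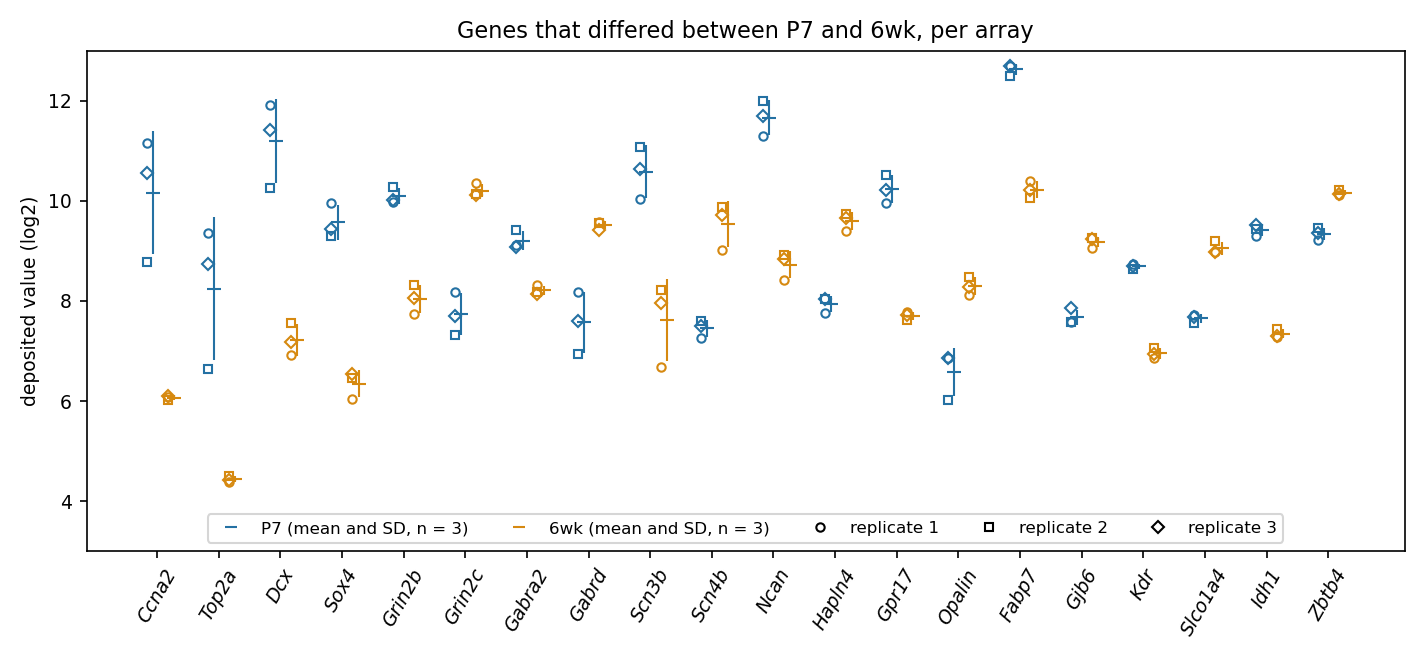
Deposited log2 value (vertical axis) of 20 genes (horizontal axis) on each array, blue for P7 and orange for 6wk; open symbols are replicates, and the bars give the mean and SD (n = 3). Ccna2 falls from a mean of 10.16 to 6.06 and Grin2c rises from 7.74 to 10.20, while P7 replicate 2 (squares) lies below the other P7 arrays for Ccna2, Top2a and Dcx.

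Cell cycle genes fell as a group. Of 43 measured members, 32 fell, 0 rose and 11 did not pass; adjusted over the list alone, 34 fell. The median log2 difference was -1.58, and camera placed the list below other genes (adjusted p = 1.02e-10; adjusted p = 0.432 with an estimated correlation). In P7 replicate 2 the median member was lower than in P7 replicate 1 by a log2 difference of -1.47. Without that array 40 members fell, 0 rose, and the median was -1.95.

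Granule neuron progenitor and Sonic hedgehog genes showed the strongest dependence on P7 replicate 2, where their median lay at -1.60 against P7 replicate 1. With all arrays, 5 of 21 measured members fell and 1 rose, with 8 and 1 adjusted over the list alone, and the list did not pass (median -0.48, camera adjusted p = 0.109; adjusted p = 0.817 with an estimated correlation). With all arrays it passed after centring on array medians (-0.38, adjusted p = 0.0198), after a further quantile normalization (-0.38, 0.0327) and with array weights (-0.70, 0.00865), and without dim rows its median turned to 0.03 (0.875). With P7 replicate 1 alone the list median was -0.99. Mycn, a proto-oncogene that Sonic hedgehog induces in these progenitors, fell by 2.10 (SE 0.30, limma adjusted p = 0.00507). Mfap4 differed by -2.76, and by -3.67 without P7 replicate 2; its call was lost on leaving out any other array (adjusted p from 0.0658 to 0.129). The other calls were Gli3 (-0.45), Smo (-0.87) and Insm1 (-1.45), all named after their values were seen, and Ptch1, the Sonic hedgehog receptor, which differed by 0.52 in the opposite direction. Each of these lost its call in at least 3 of the 6 fits that leave out an array, for Ptch1 without P7 replicate 3 or any 6wk array (adjusted p from 0.0799 to 0.146). Without P7 replicate 2, 14 members fell, 1 rose, and the list passed (median -0.85, camera adjusted p = 7.23e-06; adjusted p = 0.400 with an estimated correlation).

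Genes of immature neurons, axon growth and migration fell together. Of 30 measured members 19 fell and 0 rose, and 23 fell adjusted over the list alone. Sox4, a transcription factor of newborn neurons, fell from 9.57 ± 0.35 (SD, n = 3) to 6.35 ± 0.28 (SD, n = 3), a log2 difference of -3.22, alongside Dcx. The list median was -1.18 (camera adjusted p = 3.34e-09; adjusted p = 0.329 with an estimated correlation), and -1.19 with 25 falls without P7 replicate 2. This group was lower in P7 replicate 2 than in P7 replicate 1 by a median of -0.43.

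Mature granule neuron genes rose in 11 of 20 measured members, none fell, and the count adjusted over the list alone was also 11. Grin2c, the NMDA receptor subunit of mature granule neurons, rose from 7.74 ± 0.43 (SD, n = 3) to 10.20 ± 0.13 (SD, n = 3), a log2 difference of 2.47 (SE 0.21, limma adjusted p = 0.00121). The median was 1.18 (camera adjusted p = 4.65e-08; adjusted p = 0.329 with an estimated correlation). These genes were lower in P7 replicate 2 than in P7 replicate 1 by a median of -1.26, and without that array the list median was 0.90 with 13 rises. Gabra6 differed by 3.74 and did not pass with all arrays (adjusted p = 0.10), whereas without P7 replicate 2 it rose by 2.05 (adjusted p = 0.00841).

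Purkinje cell genes rose in 6 of 20 measured members and fell in 0, with 7 and 1 adjusted over the list alone. Rgs8, a regulator of G protein signalling, rose by 1.49 (SE 0.17, limma adjusted p = 0.00259). Pvalb, the calcium buffer parvalbumin, differed by 1.85, and its call was lost without P7 replicate 3 or any 6wk array (adjusted p from 0.0590 to 0.0618). The list median was 0.55 (camera adjusted p = 0.000528; adjusted p = 0.329 with an estimated correlation) and 0.42 without P7 replicate 2, in which the list was lower than in P7 replicate 1 by a median of -0.65. GABAergic interneuron genes did not pass (median 0.01 over 16 members, camera adjusted p = 0.351): with or without adjustment over the list alone the single call was Prkcd, a protein kinase C, which rose by 1.00. In P7 replicate 2 the interneuron list was higher than in P7 replicate 1 by a median of 0.70, and without it the median was 0.28 with 3 rises and 2 falls. With P7 replicate 1 alone the interneuron median was 0.36.

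Receptor and channel subunits changed in both directions. Of 15 ionotropic glutamate receptor subunits 4 rose and 2 fell, and 4 and 4 adjusted over the list alone. Grin2b fell from 10.09 ± 0.16 (SD, n = 3) to 8.04 ± 0.29 (SD, n = 3), a log2 difference of -2.05 (SE 0.17, limma adjusted p = 0.000962), while Grin2a rose by 0.72 (adjusted p = 0.00899) and Grin2c by 2.47. The other calls were Gria1 (0.51) and Gria4 (0.48), named after their values were seen, and Grik1 (-1.01), and each of these was lost on leaving out single arrays, with adjusted p up to 0.0842, 0.134 and 0.0786. The list did not pass (median -0.11, mean -0.09, camera direction higher, adjusted p = 0.736; median -0.10 without P7 replicate 2). Of 10 GABA-A receptor subunits and chloride transporters, Gabrd, a subunit of extrasynaptic receptors, rose by 1.95 and Gabra2 fell by 0.99, each also called in every fit that left out an array. Gabrb2 differed by 0.71 and lost its call without P7 replicate 3 or any 6wk array (adjusted p from 0.0893 to 0.104). The list as a whole, with 2 rises and 1 fall also when adjusted over the list alone, did not pass (median 0.04, camera adjusted p = 0.729; median 0.08 without P7 replicate 2).

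Among 23 voltage-gated potassium and sodium channel genes 11 rose and 3 fell, and 13 and 6 adjusted over the list alone. Scn4b and Scn2b, sodium channel beta subunits, rose by 2.08 and 1.42, whereas the beta subunit Scn3b fell by 2.97 (SE 0.45, limma adjusted p = 0.00649) and the potassium channel Kcnq5 by 2.69. The call of Scn3b was lost with P7 replicate 1 alone (-2.42, adjusted p = 0.0619). The remaining fall was Scn3a (-2.39), named after its value was seen, whose adjusted p reached 0.0722 when single arrays were left out. The list median was 0.42 and its mean 0.04 (camera adjusted p = 0.00559; adjusted p = 0.405 with an estimated correlation). Synaptic genes rose in 9 of 28 members, 11 adjusted over the list alone, with 0 falls (median 0.14, camera adjusted p = 0.000288; adjusted p = 0.405 with an estimated correlation). They included Nptx1, a neuronal pentraxin, up by 2.03, and Syt2, a synaptic vesicle calcium sensor, up by 1.21. Both lists were higher in P7 replicate 2 than in P7 replicate 1, by medians of 0.70 and 0.29; without it their medians were 0.39 and 0.27.

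Oligodendrocyte genes moved in opposite directions by stage. Of 14 precursor genes 9 fell and 0 rose, and 13 fell adjusted over the list alone (median -0.90, camera adjusted p = 5.38e-06; adjusted p = 0.329 with an estimated correlation). Gpr17, a receptor of committed precursors, fell from 10.23 ± 0.28 (SD, n = 3) to 7.70 ± 0.08 (SD, n = 3), a log2 difference of -2.53, and Pdgfra, the precursors' growth factor receptor, fell by 1.59. Of 23 myelin and mature oligodendrocyte genes 11 rose and 0 fell, also when adjusted over the list alone (median 0.52, camera adjusted p = 2.22e-05; adjusted p = 0.432 with an estimated correlation). Ermn, a cytoskeletal protein of myelinating cells, rose by 1.95 and Opalin, a myelin membrane protein, by 1.72. The major myelin gene Mbp, named after its value was seen, read 10.92 ± 0.14 (SD, n = 3) and 10.81 ± 0.07 (SD, n = 3) and did not pass (adjusted p = 0.471). Precursor genes were higher (median 0.48) and myelin genes lower (median -0.29) in P7 replicate 2 than in P7 replicate 1. In P7 replicate 3 both were higher than in P7 replicate 1 (medians 0.27 and 0.18). Without P7 replicate 2 the list medians were -0.73 and 0.37, and with P7 replicate 1 alone they were -0.58 and 0.53.

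Bergmann glia and astrocyte genes split, with 7 rises and 5 falls among 23 members, and 9 and 5 adjusted over the list alone. Gjb6, connexin 30, rose by 1.51 (SE 0.11, limma adjusted p = 0.000775) and the calcium-binding protein S100b by 1.16, whereas Fabp7, the fatty acid-binding protein of radial and Bergmann glia, fell from 12.63 ± 0.11 (SD, n = 3) to 10.22 ± 0.17 (SD, n = 3), a log2 difference of -2.41. The other falls were Gfap (-0.84) and, named after their values were seen, Aqp4 (-0.63), Aldh1l1 (-0.79) and Nes (-0.33). Each of these was lost on leaving out single arrays, with adjusted p up to 0.0899, 0.0597, 0.0506 and 0.141. The median was 0.38 (camera adjusted p = 0.00649; adjusted p = 0.329 with an estimated correlation) and 0.19 without P7 replicate 2, and the call was lost with P7 replicate 1 alone (0.22, adjusted p = 0.0537).

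Extracellular matrix genes fell in 7 of 16 members and rose in 2, and in 10 and 2 adjusted over the list alone. Ncan and Tnc, which encode neurocan and tenascin C of the juvenile matrix, fell by 2.94 and 2.41, and the link proteins Hapln4 and Hapln2 rose by 1.65 and 1.45. The median was -0.80 (camera adjusted p = 0.0331; adjusted p = 0.405 with an estimated correlation). That call was lost without P7 replicate 3 (adjusted p = 0.0551) or 6wk replicate 1 (0.0710) and held without P7 replicate 2 (median -0.59), in which the list was higher than in P7 replicate 1 by a median of 0.57 (0.35 in P7 replicate 3). It was also lost with P7 replicate 1 alone (median -0.29, adjusted p = 0.0618) and without dim rows (-0.79, 0.226).

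Cholesterol genes fell in 14 of 17 members and rose in 0, with 15 falls adjusted over the list alone (median -0.77, camera adjusted p = 5.33e-09; adjusted p = 0.329 with an estimated correlation). Sqle, squalene epoxidase, fell from 10.40 ± 0.10 (SD, n = 3) to 8.77 ± 0.14 (SD, n = 3), a log2 difference of -1.64 (SE 0.11, limma adjusted p = 0.000644), and Nsdhl, a later enzyme of the pathway, by 1.32. The list differed between P7 replicates 2 and 1 by a median of 0.00, and its median without P7 replicate 2 was -0.73. Glycolysis genes rose in 6 of 17 members and fell in 1, with 8 and 1 adjusted over the list alone (median 0.25, camera adjusted p = 0.00360; adjusted p = 0.405 with an estimated correlation; median 0.29 without P7 replicate 2). Aldoc, aldolase C, rose by 1.06 and Ldha, lactate dehydrogenase A, fell by 0.60. Mitochondrial respiration genes did not pass (median -0.03 over 38 members, camera direction higher, adjusted p = 0.952), with a median of -0.01 without P7 replicate 2. The 3 calls were Sdha (0.49), Sdhd (-0.28) and Atp5g1 (-0.36), of which Sdha alone stayed when adjusted over the list alone, and all 3 were lost on leaving out single arrays (adjusted p up to 0.0564, 0.161 and 0.123).

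Vascular and meningeal genes were mostly lower at 6wk. Of 19 endothelial and pericyte genes 12 fell and 3 rose, and 14 and 3 adjusted over the list alone (median -0.49, camera adjusted p = 0.00644; adjusted p = 0.405 with an estimated correlation). Kdr, the VEGF receptor, fell by 1.74 (SE 0.09, limma adjusted p = 0.000478) and Cldn5, a tight junction claudin, by 1.21. The 3 rises were in transporters of the blood-brain barrier: Slco1a4 (1.40), the glucose transporter Slc2a1 (0.65) and, named after its value was seen, Abcb1a (0.56). The last 2 lost their calls on leaving out single arrays (adjusted p up to 0.101 and 0.0504). Slco1c1, also such a transporter and named after its value was seen, was among the falls (limma adjusted p = 0.00630). It kept its call in each fit that left out an array. Of 13 meningeal and fibroblast genes 8 fell and 0 rose, also when adjusted over the list alone (median -0.51, camera adjusted p = 0.000528; adjusted p = 0.329 with an estimated correlation). Postn, periostin, fell by 2.01 and Igfbp2, an insulin-like growth factor binding protein, by 1.46. Without P7 replicate 2 the medians of these lists were -0.44 and -0.67. The endothelial call was lost with P7 replicate 1 alone (-0.48, adjusted p = 0.0537) and without dim rows (-0.52, 0.147).

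Microglial genes fell in 4 of 18 members and rose in 0, with 5 falls adjusted over the list alone (median -0.26, camera adjusted p = 0.0156; adjusted p = 0.405 with an estimated correlation). Fcrls fell by 1.26 and Mrc1, the mannose receptor of border macrophages, by 0.76. The others were Cd68 (-0.63) and Tyrobp (-0.53), named after their values were seen, which lost their calls on leaving out single arrays (adjusted p up to 0.0538 and 0.0977). Antigen presentation and complement genes rose in 3 of 12 members and fell in 1, and in 6 and 1 adjusted over the list alone (median 0.20, camera adjusted p = 0.0156; adjusted p = 0.329 with an estimated correlation). Ifit3 and Ifi27, both interferon-induced, rose by 2.19 and 0.84. Cd74 (0.54), named after its value was seen, and Tap1 (-0.41) lost their calls on leaving out single arrays (adjusted p up to 0.141 and 0.0931). Without P7 replicate 2 the medians were -0.21 for microglia and 0.21 for antigen presentation, and both calls were lost with P7 replicate 1 alone (-0.17 and 0.23, adjusted p = 0.0868 and 0.0599).

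Among the genes that write, read or remove DNA methylation, 7 of 22 measured members fell and 2 rose, also when adjusted over the list alone. The list did not pass as a whole (median -0.13, camera adjusted p = 0.351; adjusted p = 0.817 with an estimated correlation). Tet2 read 9.24 ± 0.01 (SD, n = 3) at P7 and 9.09 ± 0.12 (SD, n = 3) at 6wk, a log2 difference of -0.15 that did not pass (SE 0.09, limma adjusted p = 0.289). Tet3 read 9.75 ± 0.26 (SD, n = 3) and 9.54 ± 0.06 (SD, n = 3), a difference of -0.21 that did not pass either (SE 0.14, adjusted p = 0.344; -0.34 and 0.0717 without P7 replicate 2). Tet3 differed by -0.47 with P7 replicate 1 alone and by -0.08 without P7 replicate 1 (limma adjusted p = 0.639). With array weights, whose fit did not converge, Tet2 (-0.18, adjusted p = 0.0148) and Tet3 (-0.21, 0.00873) passed. Tet1 was not analysed here. The maintenance methyltransferase Dnmt1 differed by -0.42 (adjusted p = 0.0441) and the de novo methyltransferase Dnmt3a by -0.85 (adjusted p = 0.0367). Both calls held without P7 replicate 2 (-0.51 and -0.64). Both were lost without P7 replicate 3 (adjusted p = 0.134 and 0.119) and without any 6wk array (0.0994 to 0.132), and that of Dnmt1 also without P7 replicate 1 (0.0545). The calls were also lost after centring on array medians (0.0902 and 0.0608), after a further quantile normalization (0.0575 and 0.0695) and with the replicate number as a block (0.0660 and 0.0613), and that of Dnmt3a with P7 replicate 1 alone (-0.39, 0.0941). Dnmt3b did not pass (-0.19, adjusted p = 0.382), nor did it without P7 replicate 1 (-0.05, 0.733). It differed by -0.47 with P7 replicate 1 alone, and it passed with array weights (-0.16, adjusted p = 0.0247). Idh1, which makes the 2-oxoglutarate that TET enzymes consume, fell from 9.41 ± 0.11 (SD, n = 3) to 7.34 ± 0.09 (SD, n = 3), a log2 difference of -2.07 (adjusted p = 0.000419). Uhrf1, the partner of Dnmt1 at replicated DNA, differed by -1.72 and lost its call without P7 replicate 3 or any 6wk array (adjusted p from 0.0658 to 0.0762). Zbtb4, a protein that binds methylated DNA, and Gadd45b, a stress-induced gene, rose by 0.82 and 0.81. The list was lower in P7 replicate 2 than in P7 replicate 1 by a median of -0.34; without it, 7 fell and 3 rose (median -0.17, camera adjusted p = 0.0751). With P7 replicate 1 alone the list median was -0.30.

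Imprinted growth genes fell in 6 of 13 members and rose in 1, and in 8 and 1 adjusted over the list alone (median -0.61, camera adjusted p = 0.0121; adjusted p = 0.405 with an estimated correlation). Mest fell by 2.14 and Nnat by 1.65, while Igf2r, the receptor that clears IGF2, differed by 0.44 and lost its call without P7 replicate 3 or any 6wk array (adjusted p from 0.102 to 0.130). In P7 replicate 2 the list was higher than in P7 replicate 1 by a median of 0.63, and in P7 replicate 3 by 0.51. Without P7 replicate 2 the median was -0.47 (camera adjusted p = 0.0473), and the call was lost with P7 replicate 1 alone (median -0.41, adjusted p = 0.346) and without dim rows (-0.42, 0.141). Immediate early genes, which neuronal activity induces, passed as a list (median 0.22 over 17 members, camera adjusted p = 0.0199; adjusted p = 0.432 with an estimated correlation), and had a median of 0.25 without P7 replicate 2. Their 2 calls were Egr1 (0.79) and Arc (0.44), which were not called adjusted over the list alone and were lost on leaving out single arrays (adjusted p up to 0.0971 and 0.134); the list lost its call without 6wk replicate 1 (median 0.11, adjusted p = 0.0765) and with array weights (0.16, 0.0510).

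The remaining lists did not pass. Ribosome biogenesis genes had a median of -0.16 over 19 members (camera adjusted p = 0.135). Without P7 replicate 2 the list passed (median -0.19, camera adjusted p = 0.0295, or 0.445 with an estimated correlation). With P7 replicate 1 alone the list had a median of -0.19. Of its 3 calls, Nop58 (-0.52), Nhp2 (-0.37) and, named after its value was seen, Nop56 (-0.32), none was called adjusted over the list alone, and each was lost on leaving out single arrays (adjusted p up to 0.146, 0.154 and 0.146). Choroid plexus and ependymal genes had a median of 0.05 over 10 members (adjusted p = 0.595), turning to -0.06 without P7 replicate 2, in which they were lower than in P7 replicate 1 by a median of -1.13. Otx2 (-0.71) was their single call. Blood cell genes had a median of -0.13 over 8 members (adjusted p = 0.876) and of -0.02 without P7 replicate 2, with Slc4a1 (-0.40) as the single call, which was lost without P7 replicate 2 (-0.34, adjusted p = 0.0734). Neither call stood adjusted over the list alone, and both were lost on leaving out further arrays (adjusted p up to 0.110 and 0.152). Genes of tissue next to the cerebellum had no call with either adjustment among 13 members by limma (1 at an unadjusted p under 0.05), with a median of -0.11 (adjusted p = 0.729), and -0.34 with 1 fall without P7 replicate 2.

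**Figure D3:**
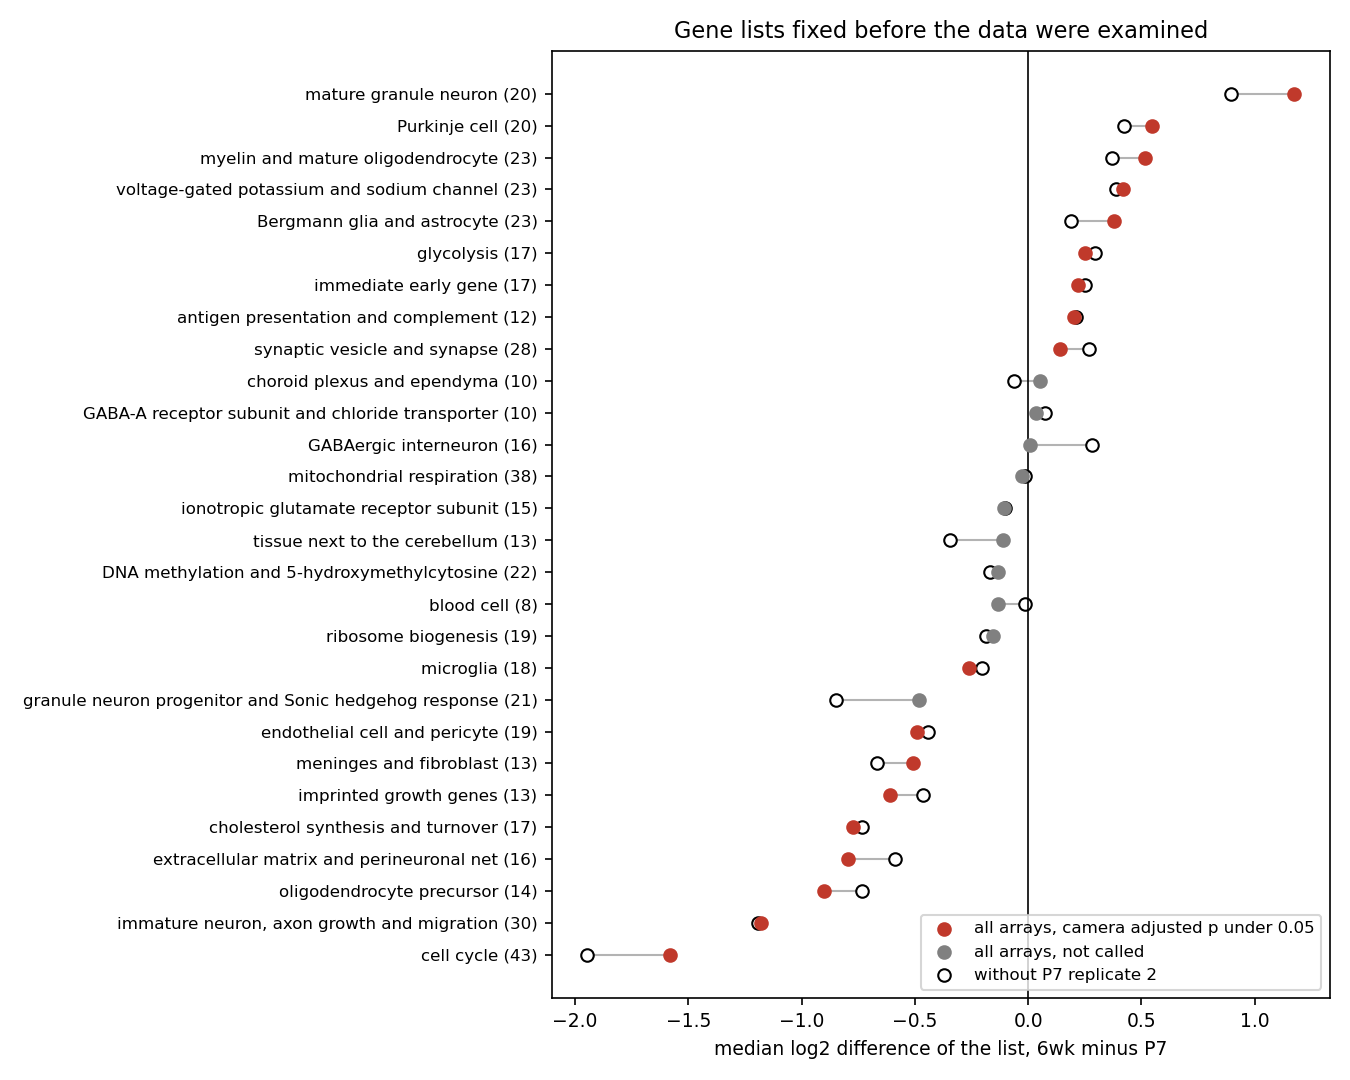
Median log2 difference, 6wk minus P7 (horizontal axis), of 28 gene lists (vertical axis, measured members in brackets): filled points use all 6 arrays, red where camera with its preset correlation passed, and open points leave out P7 replicate 2. With all arrays 18 lists passed, from cell cycle (-1.58) to mature granule neuron (1.18), and 0 passed with an estimated correlation.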

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

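Leaving out P7 replicates 2 and 3 together was the alternative chosen after the data were seen; the others were planned. Named genes were not run with the unequal-variance test, and 59 of the 81 have a value without dim rows; in the other alternatives none changed direction. The number of named genes that lost their call was 25 without P7 replicate 3, 22 or 23 without each 6wk array, 5 without P7 replicate 1, 2 without P7 replicate 2, 11 with the replicate block, 9 after centring, 8 with P7 replicates 2 and 3 left out, 7 after quantile normalization and 1 when rows of a gene were averaged. Calls were gained for 3 with array weights (Tet2, Tet3, Dnmt3b) and 2 with P7 replicates 2 and 3 left out (Tet3, Dnmt3b). Signal over background was not measured. A group mean below the first quartile of every array (6.89) was found for 17 of the 81, whose differences are uncertain in size, and the 59 with a value without dim rows stayed on the same side of the threshold. For the changes in calls the cause was not tested.

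Array weights, whose fit did not converge, gave 4425 genes higher and 6933 lower at 6wk, and 5343 and 8415 transcript clusters, with the counts of at least 2-fold differences within 1.5 times. The unequal-variance test, which shares no spread across rows, gave 431 and 594 genes (120 and 168 of them at least 2-fold) and 385 and 560 clusters (119 and 167 at least 2-fold). Without the dim rows, which tests fewer rows, 313 genes and 436 clusters were at least 2-fold lower. Leaving out each array in turn gave 682 to 1788 genes higher, 965 to 3073 lower and 387 to 873 at least 2-fold lower, and 641 to 1847, 923 to 3573 and 443 to 996 clusters.

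Replicate numbers showed no clear pairing: same-numbered deviations from the group means correlated at 0.20, 0.10 and -0.07 (across rows). Not every array correlated best with its own number. The deviations of P7 replicates 1 and 2 correlated at -0.88 with each other. That contrast could hide a weaker pairing, so these values cannot exclude one. With the replicate number as a block (replicate block) 3273 genes were called, 1199 higher and 2074 lower, no list changed its call, and 11 named genes were no longer called.

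With an estimated correlation, which leaves each median as it was, 18 lists lost their call: mature granule neuron (1.18), Purkinje cell (0.55), myelin (0.52), channels (0.42), Bergmann glia (0.38), glycolysis (0.25), immediate early genes (0.22), antigen presentation (0.20), synapse (0.14), microglia (-0.26), endothelial cells (-0.49), meninges (-0.51), imprinted genes (-0.61), cholesterol (-0.77), extracellular matrix (-0.80), oligodendrocyte precursors (-0.90), immature neurons (-1.18) and cell cycle (-1.58). Fry also lost immediate early genes (0.22, adjusted p = 0.217).

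The progenitor list gained a call after centring (-0.38, adjusted p = 0.0198), quantile normalization (-0.38, 0.0327) and array weights (-0.70, 0.00865), and its median turned to 0.026 without dim rows. Mitochondrial respiration turned to 0.069 after centring and 0.088 after quantile normalization, and glutamate receptors to 0.017 after quantile normalization; neither list passed. Array weights turned interneurons to -0.063 and choroid plexus to -0.0093, both not passing, and ended the call of immediate early genes (0.16, adjusted p = 0.0510). Without dim rows endothelial cells (-0.52), extracellular matrix (-0.79) and imprinted genes (-0.42) lost their calls with fewer members.

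Other lists kept their call while the median moved more than 1.5 times. These were synapse (from 0.14 to 0.28 after quantile normalization, 0.24 after centring and 0.44 with P7 replicates 2 and 3 left out), microglia (from -0.26 to -0.17 after quantile normalization, -0.16 after centring and -0.40 without dim rows), myelin (0.31 with array weights), cell cycle (-1.04), channels (0.75) and immediate early genes (0.61) without dim rows, and oligodendrocyte precursors (-0.58) with P7 replicates 2 and 3 left out. The same held for synapse (0.27) and Bergmann glia (0.19) without P7 replicate 2 and for glycolysis (0.15) without P7 replicate 1.

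With P7 replicates 2 and 3 left out, P7 replicate 1 stood alone and was assumed to vary like the 6wk arrays. Calls were then lost for Bergmann glia (0.22), antigen presentation (0.23), endothelial cells (-0.48), extracellular matrix (-0.29), imprinted genes (-0.41) and microglia (-0.17). Calls were gained for the progenitor list (-0.99), DNA methylation (-0.30), interneurons (0.36) and ribosome biogenesis (-0.19). Medians that passed neither way turned to -0.017 for GABA-A receptors, 0.16 for blood cells, -0.18 for choroid plexus and 0.037 for glutamate receptors.

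Leaving out each array in turn, list medians ranged from -0.086 to 0.35 for choroid plexus, -0.91 to -0.59 for extracellular matrix, 0.11 to 0.30 for immediate early genes, -0.34 to 0.011 for tissue next to the cerebellum, -0.15 to 0.089 for GABA-A receptors, -0.079 to 0.28 for interneurons, -0.85 to -0.38 for the progenitor list and -0.19 to -0.13 for ribosome biogenesis. The remaining lists kept their direction and call in each of these fits.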

Other observations

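The tests of P7 replicates 2 and 3 and of gene families below were chosen after the data were seen, except that the midbrain gene list was fixed before its values were looked at and the splits of the arrays were planned. Ribosomal protein genes were lower at 6wk: 26 of 52 fell and 0 rose (median log2 difference -0.52 as deposited, -0.42 after centring, -0.61 without P7 replicate 2; limma camera p = 2.24e-10, and p = 0.114 with an estimated correlation). Their sequences are shared with many pseudogenes, so single members are uncertain.

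Of 214 families of at least 10 genes with a shared symbol stem, 9 passed camera, 2 of them ribosomal protein stems. In the Rpl stem 21 of 60 fell and 0 rose (median -0.38), and in the Rps stem 14 of 39 fell and 1 rose (-0.37). Among the others, collagens fell in 18 of 42 members and rose in 0 (median -0.36, camera adjusted p = 0.000885). Inositol polyphosphate phosphatases rose in 7 of 10 and fell in 1 (median 0.52, adjusted p = 0.00164), led by Inpp5j (1.64), and carbonic anhydrases rose in 7 of 16 and fell in 1 (median 0.62, adjusted p = 0.00562), led by Car4 (1.66) and Car14 (1.58). Sox transcription factors fell in 7 of 21 members and rose in 0 (median -0.45, adjusted p = 0.0132). Protocadherins outside the gene clusters (symbol stem Pcdh and a number) fell in 6 of 11 and rose in 0 (median -1.23, adjusted p = 0.0272), a call that was lost without P7 replicate 2 (median -0.91, adjusted p = 0.116). Adamts proteases fell in 8 of 18 and rose in 1 (median -0.39, adjusted p = 0.0347). Olfactory receptors had a median level of 4.64, below the first quartile of every array. Of 837 members 27 rose and 3 fell (median 0.09 as deposited and 0.18 after centring, camera adjusted p = 0.00582). That is a smaller share of rises than over all genes, where 1475 of 17858 rose (median -0.05). Clustered beta protocadherins (Pcdhb) fell in 3 of 22 and rose in 0 and did not pass (median -0.25, adjusted p = 0.388). All these directions were the same after centring and after quantile normalization, and with an estimated correlation no family passed (adjusted p = 0.9996 for each).

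P7 replicate 2 stood apart: genes of cerebellar granule and Purkinje neurons were low in it, and Slc6a3, Th, Slc6a4 and Tph2 were high. An exchange with a 6wk array is argued against by the correlations of P7 replicate 2, at most 0.943 with 6wk arrays and 0.952 and 0.978 with P7 arrays. The margin to 0.952 is small, since P7 replicate 3 and 6wk replicate 2 reached 0.953. The 6wk arrays, 1 of which would then be a P7 array, correlated with each other at 0.984 to 0.989. A candidate explanation is tissue with little cerebellum and more midbrain. Of 18 textbook midbrain genes, 15 were higher in P7 replicate 2 than in P7 replicate 1 (median 0.49, percentile 99.99 of 10000 lists matched on level). Meis2 read 10.27 against 8.49 and Drd2 10.14 against 8.35. The matched lists hold random genes, so the percentile makes no allowance for markers that move together. It also compares 1 array with 1. Of the 18 genes, 0 are in another list here and 9 lay above the array median in P7 replicate 1. The labels give cerebellum for every array. The fixed list of tissue next to the cerebellum, which holds Slc6a4, Tph2 and Th, had a median of -0.25 with members going both ways. Its mean level was 7.47 in P7 replicate 1 and 7.88 in P7 replicate 2. Weak or degraded RNA stays open: 55 glycolysis and respiration genes had a median log2 difference from P7 replicate 1 of 0.112, but the values are normalized between arrays, which removes a general loss of signal, so this decides nothing. The labels put P7 replicate 2 in no group of its own, so beyond tissue content, weighed here as a technical matter, no biological explanation was tested.

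P7 replicate 3 lay between P7 replicates 1 and 2 for all 55 genes over 4-fold higher and all 97 over 4-fold lower in replicate 2. The share of replicate 2 that these genes give on the linear scale had a lower first quartile of 0.383. Since the genes were picked for a large difference between P7 replicates 1 and 2, another array of the tissue of replicate 1 would also tend to lie between them. The share therefore cannot decide whether P7 replicate 3 held the same tissue as P7 replicate 1. A mixture of the tissues of replicates 1 and 2 may account for these genes, which were chosen for their difference between the 2. The median share was 0.440 from the higher genes and 0.431 from the lower genes, a difference of 0.009. Of the 18 midbrain genes, not picked this way, 17 were higher in P7 replicate 3 than in P7 replicate 1 (median 0.35). The list medians of P7 replicate 3 lay between those of replicates 1 and 2 in 24 of the 28 fixed lists, but those of myelin, microglia, tissue next to the cerebellum and cholesterol lay outside. Of the myelin genes, 18 of 23 were higher than in both (median 0.14 above the higher one), which a mixture of these 2 alone does not give, beyond noise between single arrays. A dissection that took in neighbouring tissue to a different extent each time stays open beside a mixing of RNA. Beyond tissue content no biological explanation was tested.

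Among the 6wk arrays, Meis2 read 7.24, 9.17 and 8.91 and Drd2 read 7.32, 8.94 and 8.59 in replicates 1, 2 and 3, the largest differences among the 18 midbrain genes. Over all 18, 10 were higher in 6wk replicate 2 than in 6wk replicate 1 (median difference 0.04) and 14 in 6wk replicate 3 (0.10). In the same order, Tph2 read 5.66, 7.34 and 6.50 and Slc6a4 read 6.18, 7.34 and 6.59. Slc6a3 (6.73, 7.09 and 6.92) and Th (8.55, 8.75 and 8.65) differed less. These genes were chosen after their values were seen. Equal tissue content of the 6wk arrays is thus not shown. The Y-linked genes Eif2s3y and Kdm5d read 10.49 and 8.13 in 6wk replicate 1, against 5.42 to 5.66 and 6.41 to 6.61 on the other 5 arrays.

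The 6 arrays can be split into groups of 3 in 10 ways. As many calls as the real split gave, 4300 clusters and 3870 genes, came in 1 of the 10 splits, the real one, and the highest other split gave 0 of each with limma (at an unadjusted p under 0.05, at most 1156 clusters and 715 genes, against 7819 and 6371). With 10 splits the share cannot fall under 0.05. Each other split also puts both ages in each group, so the age difference adds to the spread there. Its 0 calls are therefore no measure of false calls.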
